A study of Mus musculus with 41 samples.

How the data were processed

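Expression values were the log2 normalized intensities that the authors deposited for 41 Affymetrix Mouse Gene 1.0 ST arrays hybridized with cDNA from total RNA. The labels name Partek for processing. Its version, background correction and summarization are not given in the sources used here, and no normalization was added in the main fit. Array medians lay between 5.374 and 5.483 and values between 1.916 and 13.514. Both deposited value tables held identical values in every cell. The authors' table also held p-value columns (p_value), unadjusted and step-up adjusted, which the authors made by ANOVA with contrasts before depositing it, per the file headers. These were counted at adjusted p under 0.05. Its deposited ratio columns matched ratios computed from the group means within 7e-05 log2 units. The deposited signed fold columns (other) and the F and sum-of-squares columns (score), per the file headers, were read for their unit only.

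Of 28815 probe sets 23380 were in the probe annotation and 5435 were not. Those with several genes (1598) were left out, leaving 21782 with 1 gene, of which 91 had a gene number outside the reference table and kept their symbol. The probe set with the highest mean was kept for the 999 genes with several, which gave 19938 genes. Groups were age by day as the labels give them: young (5 months) and old (25 months) at days 0, 5, 10 and 20, 5 arrays each and 6 for old day 0. Mice were distinct, and replicate numbers were names only. The sample names in the labels were sorted here into 3 numbering series (lettered, low number, high number), used to split the age contrasts and as a block. The lettered series pooled names starting with H, P, NO or NON.

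A limma 3.58.1 model in R 4.3.3 with a mean per group (8 groups, residual degrees of freedom 33) gave 13 contrasts by moderated two-sided t tests: 4 between ages, 6 between consecutive days and 3 of age by step. P values were adjusted by Benjamini-Hochberg within each contrast, and adjusted p under 0.05 was called. SE is the moderated standard error of the log2 change, and SD the spread of a group. Overlap of groups was counted for the genes called and for all genes, beside the share of arrangements in which chance gives none. Tables, permutations and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit and the list test were tested on simulated data in which 200 genes were changed. Noise was drawn independently for each gene, so the rates below do not cover correlated genes. Estimated correlations within the real lists ran from 0.072 (hypoxia) to 0.822 (erythroid). In the day 5 contrast 64.2%, 97% and 100% of shifts of 0.5, 1 and 2 were recovered with 4.9% false calls, at day 0 61.2%, 95.5% and 100% with 6.5%, and in the age-by-step contrast 41.8%, 80.6% and 100% with 5.7%.

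Gene lists were fixed from textbook knowledge before the data were examined: cartilage matrix, hypertrophic cartilage, osteoblast and bone matrix, osteocyte, osteoclast, fibrous matrix, matrix proteases and inhibitors, G1/S and DNA replication, G2/M and mitosis, inflammatory cytokines and mediators, interferon response, antigen presentation by MHC II, macrophage, neutrophil, B cell, plasma cell, T and NK cell, mast cell and basophil, erythroid, megakaryocyte and platelet, skeletal muscle, muscle regeneration, adipocyte, endothelial, Schwann and nerve, epidermis, BMP, Wnt and hedgehog signalling, hypoxia and glycolysis, mitochondrial respiration, senescence and secreted factors, and immediate early and heat shock. These 31 were tested by limma camera with a preset correlation of 0.01 between genes, two-sided, adjusted over lists within a contrast, and beside it with an estimated correlation and by fry. A further list of sex-linked genes had 4 measured members, under the minimum of 5, and was not tested. Members without a matching symbol were not matched here. Values of a list are medians of its members' log2 changes, and counts "alone" were adjusted over the list only.

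Genes were named by a rule fixed beforehand: the 10 highest and 10 lowest genes called without overlap in an age contrast, 8 and 8 in a time contrast, 5 and 5 in an age-by-step contrast, predicted genes skipped. Where none passed, the 5 with the smallest p were given. From each list up to 4 members that passed, or 2 that did not, were eligible. Ubd, C4b, Calml3, Scube1 and Tmeff2 were added after values were seen, to complete the genes called.

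Alternatives fixed beforehand were quantile normalization and median centring of arrays, leaving out dim genes (14953 or 9969 genes left), the mean of a gene's probe sets, an unmoderated ANOVA test, eBayes with trend and robust, a fit on the groups compared only, array quality weights, replicate or numbering series as a block, a 2-fold minimum, lists without shared members, and leaving out each array. Added later were a fit without 2 arrays, all probe sets, the skeletal muscle or erythroid list mean as a covariate in age contrasts, exact permutation of list means, covariate slopes fitted on a single day, and the age difference averaged over days. The 2 arrays left out together (old day 5 replicate 4, old day 20 replicate 3) were picked after viewing list means. The Dixon search found neither, and young day 0 replicate 2, which was kept, lay further from its group mean (Pearson correlation 0.974 against 0.9787 and 0.9784). Chance was gauged by 100 splits of the same arrays. Principal components were taken over all genes, centred. Permutation tests were exact where arrangements allowed, otherwise from 1e+05 resamples. Raw intensity files were not analysed here.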

Results

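Gene expression was measured in bones and fracture calluses of young (5 months) and old (25 months) mice before tibial fracture (day 0) and 5, 10 and 20 days after it. Each of the 8 groups held 5 arrays, except old day 0, which held 6, and each array came from a different mouse. The 41 arrays limit the precision of every value below. Changes are log2 differences between group means ± SE, limma moderated tests gave the p values, and a gene was called at adjusted p under 0.05 over 19938 genes. The extracts were whole bone or callus alone, and which array held which is not given, so the step from day 0 to day 5 may also cross a change of tissue. Contrasts, gene lists and the rule for naming genes were fixed before the data were examined.

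Day separated the arrays far more than age did. The first principal component carried 52.4% of the variance and day accounted for 92.5% of it. Component 2 carried 12.5% (day 90.5%). On component 1 the mean score of young mice went from −59 at day 0 to 39.6 at day 10 and back to 19.1 at day 20, and that of old mice from −62.6 to 48.7 and 7.3. Between ages within a day the smallest exact permutation p was 0.0079, for component 2 at day 20, where the ages did not overlap. It is the smallest p that 5 against 5 arrays allow, so on its own it could not pass over 16 tests (adjusted p = 0.13).

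**Figure D1:**
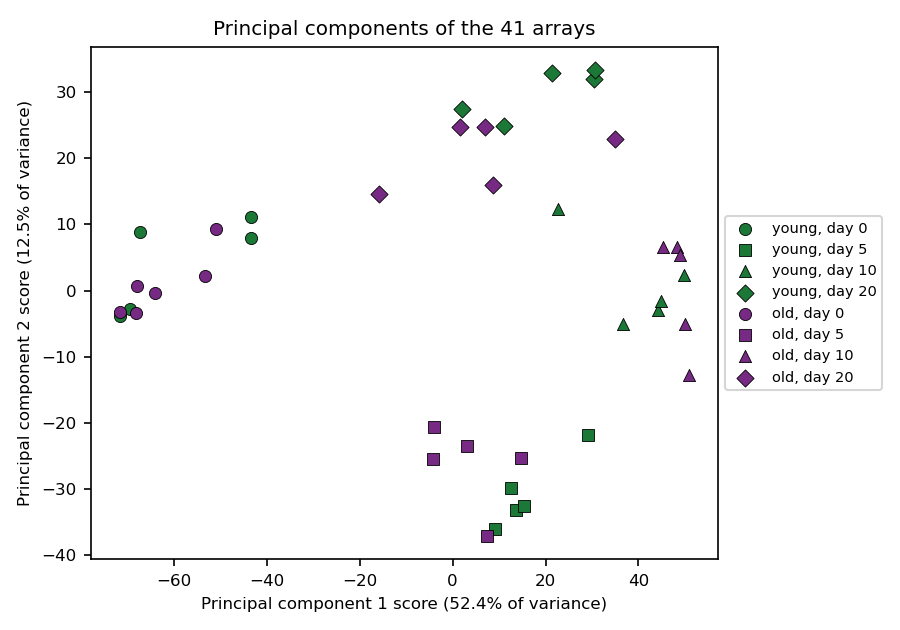
Scores of the 41 arrays on the first and second principal component. Green, young; purple, old; the marker gives the day.

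From day 0 to day 5 young bones gained chemokine, matrix and regeneration transcripts and lost red-cell, neutrophil, B-cell and platelet transcripts. The monocyte chemoattractants Ccl8 (5.69 ± 0.33, from 4.39 to 10.08) and Ccl7 (4.52 ± 0.39) rose furthest. The protease inhibitor Timp1 (4.28 ± 0.29), the hyaluronan-binding Tnfaip6 (4.21 ± 0.32), the Wnt antagonist Sfrp1 (4.18 ± 0.37), the acute-phase gene Saa3 (4.14 ± 0.34), Ms4a6d (4.11 ± 0.31) and the neutrophil attractant Cxcl5 (4.09 ± 0.44) followed. The red-cell genes Rhag (−4.96 ± 0.67), Car1 (−4.91 ± 0.66), Cldn13 (−4.64 ± 0.56), Car2 (−4.48 ± 0.53), Ctse (−4.48 ± 0.60), Kel (−4.45 ± 0.53) and Rhd (−4.43 ± 0.56) fell furthest, as did the neutrophil marker Ly6g (−4.35 ± 0.53). All 16 had an adjusted p of 1.7e-07 or less and kept their call under every alternative. In all, 7229 genes were called in young mice, 3987 higher and 3242 lower. Of these 4403 had no overlap between the groups. Over all genes, called or not, 4551 (22.8%) had none, where chance alone gives 0.794%, and later shares and chance shares are over all genes too.

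Several lists rose in young mice, and only that of secreted factors held with an estimated correlation between genes. Of 23 fibrous matrix genes 21 rose (21 adjusted over the list alone), among them Cthrc1 (3.74 ± 0.37), the crosslinking enzyme Lox (3.62 ± 0.26) and Fbln2 (3.10 ± 0.22), camera adjusted p = 1.2e-16, adjusted p = 0.098 with an estimated correlation between genes. The latter is given below as "estimated", and counts adjusted over the list alone as "alone". Of 26 macrophage genes 18 rose and 2 fell, counts unchanged over the list alone, with Clec4n (3.43 ± 0.31), Arg1 (3.22 ± 0.28) and the complement gene C1qa (2.87 ± 0.28) furthest, adjusted p = 3.9e-10, 0.098 estimated. Among 36 inflammatory genes 23 rose and 4 fell (23 and 4 alone, adjusted p = 1.3e-07, 0.098 estimated). The protease list had 13 of 19 higher and 2 lower (14 and 2 alone), with Mmp3 at 2.32 ± 0.23 and the neutrophil collagenase Mmp8 at −3.41 ± 0.34 (adjusted p = 3.1e-07, 0.098 estimated). Muscle regeneration genes rose in 9 of 10 (9 alone), including the fusion gene Mymk (3.54 ± 0.29) and Myog (3.49 ± 0.30), adjusted p = 8.8e-08, 0.098 estimated. The list of senescence and secreted factors had 10 of 16 higher and 1 lower (same alone), with Il6 at 3.39 ± 0.44 and Igfbp3 at 2.28 ± 0.22 (adjusted p = 1.1e-06, 0.031 estimated). Osteoblast genes rose in 11 of 19 (11 alone), for example Ibsp (1.78 ± 0.29), adjusted p = 0.0021, 0.63 estimated. Endothelial genes rose in 15 of 23 and fell in 3 (same alone), with Aplnr at 1.89 ± 0.23 and Cdh5 at 1.46 ± 0.17 (adjusted p = 0.00062, 0.48 estimated). Interferon genes rose in 17 of 29 and fell in 3 (18 and 4 alone, adjusted p = 0.0019, 0.63 estimated). Cartilage (6 up and 2 down of 25, 8 and 2 alone, Acan 2.62 ± 0.50) and hypoxia genes (8 up and 1 down of 23, same alone, Hif1a 2.37 ± 0.23) had adjusted p = 0.037 and 0.035, 0.69 and 0.36 estimated. Both calls depended on single arrays: cartilage lost its call without young day 0 replicate 1 or 3 or day 5 replicate 5, and hypoxia without day 0 replicate 3.

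Marrow lists fell in young mice. All 20 erythroid genes fell (20 alone, adjusted p = 9.8e-18, 0.098 estimated), as did 20 of 21 neutrophil genes, for example Ltf (−3.44 ± 0.48) and Elane (−3.07 ± 0.45); 20 alone, adjusted p = 1.5e-13, 0.10 estimated. Among 24 B-cell genes 22 fell and 1 rose (same alone), led by the pre-B-cell genes Vpreb1 (−4.20 ± 0.34) and Vpreb3 (−3.60 ± 0.32), adjusted p = 4.8e-13, 0.10 estimated. Platelet genes fell in 10 of 11 (10 alone, Gp5 −3.31 ± 0.39, adjusted p = 2.5e-07, 0.20 estimated). Cell-cycle genes fell as well: 20 of 39 mitosis genes (20 alone, Mki67 −1.76 ± 0.28, Nusap1 −1.39 ± 0.24, adjusted p = 1e-04, 0.63 estimated) and 17 of 30 replication genes against 1 higher (19 and 1 alone, Cdc6 −1.83 ± 0.29, adjusted p = 0.00017, 0.63 estimated). With the erythroid list mean as a covariate, which itself changed with day, these medians turned from −0.55 to 0.70 and from −0.62 to 0.71. Many lists of time contrasts turned in this fit, which used a single slope for all days. At day 5 the mitosis and erythroid list means had a Pearson correlation of −0.01, or 0.49 within ages. The turn therefore cannot show how division genes changed apart from red-cell genes. T and NK genes fell in 10 of 29 (10 alone, Nkg7 −3.25 ± 0.47, adjusted p = 0.0011, 0.63 estimated) and mast and basophil genes in 6 of 12 against 2 higher (same alone, Mcpt8 −3.50 ± 0.37, adjusted p = 0.019, 0.40 estimated). Mature muscle genes fell in 14 of 29 (15 alone, Myoz1 −1.56 ± 0.37), while the embryonic myosin Myh3 rose by 4.02 ± 0.35 (2 higher, adjusted p = 0.0041, 0.69 estimated). Respiration genes fell in 13 of 30 (15 alone, adjusted p = 0.00023, 0.63 estimated). Lists of hypertrophic cartilage (3 up), osteocytes (2 up, 3 down), osteoclasts (6 up, 2 down), MHC II (5 and 2), plasma cells (5 and 5), adipocytes (3 and 3), Schwann cells (3 and 1), epidermis (1 up), morphogen signalling (8 and 3) and immediate early genes (9 and 2) did not pass.

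Old bones were compared over the same days. Timp1 (4.03 ± 0.27), Tnfaip6 (3.98 ± 0.31), Ccl7 (3.97 ± 0.37), the joint lubricant Prg4 (3.85 ± 0.41), Cthrc1 (3.82 ± 0.36), the proteoglycan Vcan (3.77 ± 0.26), Ccl8 (3.63 ± 0.32) and Sfrp1 (3.49 ± 0.35) rose furthest. The eosinophil genes Ear6 (−3.88 ± 0.44) and Prg2 (−3.56 ± 0.49), Vpreb1 (−3.58 ± 0.32), Vpreb3 (−3.52 ± 0.31), Ly6g (−3.33 ± 0.51), Rhag (−3.27 ± 0.64), the basophil protease Mcpt8 (−3.14 ± 0.35) and Rhd (−3.10 ± 0.53) fell furthest, all 16 at adjusted p of 1e-04 or less. The count was 6790 (3647 higher, 3143 lower). Of these 3561 had no overlap, as had 18.3% of all genes (chance share 0.433% with 5 and 6 arrays). All 23 fibrous matrix genes rose (23 alone, adjusted p = 1.5e-19, 0.12 estimated). Among inflammatory genes 20 of 36 rose against 5 lower (21 and 5 alone, adjusted p = 2.2e-06, 0.15 estimated), and 15 of 26 macrophage genes against 4 lower (16 and 5 alone, adjusted p = 8.4e-05, 0.19 estimated). So did 13 of 19 protease genes against 2 lower (same alone, adjusted p = 2.5e-07, 0.12 estimated) and 8 of 10 muscle regeneration genes (9 alone, adjusted p = 2.1e-08, 0.12 estimated). Osteoblast genes rose in 11 of 19 (13 alone, adjusted p = 8.8e-05, 0.43 estimated) and endothelial genes in 15 of 23 against 2 lower (17 and 2 alone, adjusted p = 2.1e-06, 0.19 estimated). Secreted factors rose in 8 of 16 against 1 lower (9 and 1 alone, adjusted p = 1.3e-05, 0.089 estimated) and hypoxia genes in 9 of 23 against 1 lower (same alone, adjusted p = 0.0055, 0.15 estimated). Immediate early genes passed at adjusted p = 0.048 (10 up, 2 down, same alone; 0.48 estimated), a call that ended without any of 5 single arrays.

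The marrow lists of old mice fell. All 20 erythroid genes (20 alone, adjusted p = 8.5e-13, 0.15 estimated) and 19 of 21 neutrophil genes fell (20 alone, adjusted p = 8.3e-11, 0.15 estimated). So did 21 of 24 B-cell genes (22 alone, adjusted p = 4.3e-14, 0.14 estimated) and 10 of 11 platelet genes (11 alone, adjusted p = 2.4e-09, 0.15 estimated), 23 of 29 T and NK genes (25 alone, Ccl5 −1.75 ± 0.40, adjusted p = 4.7e-09, 0.19 estimated) and 8 of 12 mast and basophil genes (8 alone, adjusted p = 7e-04, 0.15 estimated). Mitosis genes fell in 30 of 39 (34 alone, Mki67 −1.64 ± 0.27, adjusted p = 5.4e-11, 0.30 estimated) and replication genes in 23 of 30 (23 alone, adjusted p = 2.1e-08, 0.30 estimated). With the erythroid covariate their medians went from −0.86 to −0.01 and from −0.80 to 0.11, under the same limit as in young mice. Interferon genes did not pass as a list in old mice (3 up, 6 down), nor did MHC II (1 and 4) or mature muscle (2 and 0), where the median of −0.07 and the test differ in sign. Other lists that did not pass were cartilage (8 up), hypertrophic cartilage (6 up), osteocytes, osteoclasts, plasma cells, adipocytes, Schwann cells, epidermis, morphogen signalling and respiration.

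Between day 5 and day 10 young calluses turned to cartilage. Clec3a, a cartilage lectin, rose by 5.04 ± 0.52 (from 5.07 to 10.11), the hypertrophic collagen Col10a1 by 4.68 ± 0.38. The cartilage matrix genes Matn3 (3.50 ± 0.41), Cnmd (3.49 ± 0.36), Scrg1 (3.48 ± 0.45) and Hapln1 (3.45 ± 0.53) rose with them, beside Zim1 (2.84 ± 0.24) and Agtr2 (2.69 ± 0.34). Inflammation receded: Cxcl5 (−3.85 ± 0.44), Arg1 (−3.33 ± 0.28), Saa3 (−3.19 ± 0.34), Cxcl2 (−3.13 ± 0.47), Prg4 (−3.07 ± 0.42), Il6 (−2.54 ± 0.44), Ccl2 (−2.49 ± 0.34) and Ms4a4a (−2.29 ± 0.24) fell furthest, all 16 at adjusted p of 6.9e-05 or less. In all 4072 genes were called (2153 higher, 1919 lower), 2541 of them without overlap (15.6% of all genes, chance share 0.794%). Cartilage matrix genes rose in 20 of 25 (21 alone, adjusted p = 4.5e-18, 0.047 estimated) and hypertrophic genes in 10 of 12 (10 alone, Panx3 2.29 ± 0.42, Scin 1.60 ± 0.23, adjusted p = 5.9e-10, 0.047 estimated). Inflammatory genes fell in 17 of 36 (19 alone, adjusted p = 2.3e-11, 0.047 estimated) and macrophage genes in 13 of 26 (15 alone, the haemoglobin scavenger Cd163 −2.28 ± 0.29, Cd14 −1.70 ± 0.23, adjusted p = 4.7e-11, 0.048 estimated). These 4 lists held with an estimated correlation. Endothelial genes rose in 18 of 23 (21 alone, Kdr 1.13 ± 0.18, Tek 0.97 ± 0.14, adjusted p = 5.1e-12, 0.074 estimated). Morphogen signalling rose in 20 of 39 (23 alone), led by the hedgehog targets Ptch1 (2.53 ± 0.27) and Hhip (1.93 ± 0.13), adjusted p = 1.3e-10, 0.066 estimated.

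Division genes fell again in young calluses: 32 of 39 mitosis genes (35 alone, Kif2c −1.13 ± 0.21, adjusted p = 2.1e-19, 0.21 estimated) and 22 of 30 replication genes (25 alone, adjusted p = 4.9e-12, 0.27 estimated). Interferon genes fell in 14 of 29 (20 alone, Cxcl10 −1.68 ± 0.34, adjusted p = 9.1e-09, 0.31 estimated), MHC II in 2 of 11 (2 alone, adjusted p = 0.0048, 0.42 estimated) and muscle regeneration in 5 of 10 (7 alone, Mymk −1.81 ± 0.29, adjusted p = 2.7e-05, 0.19 estimated). Osteoblast genes rose in 10 of 19 (11 alone, Dlx5 1.62 ± 0.33, adjusted p = 9.4e-07, 0.36 estimated) and osteoclast genes in 7 of 17 (8 alone, Mmp9 2.02 ± 0.39, the fusion gene Dcstamp 1.35 ± 0.23, adjusted p = 1.5e-05, 0.31 estimated). Mature muscle rose in 12 of 29 against 1 lower (23 and 1 alone, Myl1 1.64 ± 0.32, adjusted p = 5.2e-07, 0.42 estimated) and respiration in 11 of 30 (13 alone, adjusted p = 2.1e-06, 0.42 estimated). Fibrous matrix (7 up, 1 down of 23, 8 and 2 alone, median 0.36, adjusted p = 0.0029, 0.65 estimated) and proteases (8 up, 3 down of 19, same alone, median 0.44, adjusted p = 0.014, 0.42 estimated) lost their call with the numbering series as a block. So did osteocytes (6 up, 1 down of 12, 6 and 2 alone, median 0.36, adjusted p = 0.032, 0.46 estimated), whose call also ended without day 5 replicate 4 or day 10 replicate 1 or 3. Lists of neutrophils (3 down), B cells (2 up, 3 down), plasma cells, T and NK cells, mast cells, erythroid cells (0 of 20), platelets, adipocytes, Schwann cells, epidermis, hypoxia, secreted factors (6 up, 6 down) and immediate early genes did not pass. No numbering series of sample names occurred in both young groups, and a fit with the series as a block called 1852 genes.

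Cartilage genes rose in old calluses too. Clec3a (6.18 ± 0.52, from 4.98 to 11.16), Col10a1 (5.07 ± 0.38), Matn3 (4.76 ± 0.41), Cnmd (4.52 ± 0.36), Hapln1 (4.30 ± 0.53), the aggregating proteoglycan Acan (4.05 ± 0.50), Ucma (3.96 ± 0.31) and Snorc (3.93 ± 0.39) rose furthest. Cxcl5 (−3.47 ± 0.44), Cxcl2 (−3.36 ± 0.47), Saa3 (−2.74 ± 0.34), Cd163 (−2.52 ± 0.29), Prg4 (−2.42 ± 0.42), Arg1 (−2.33 ± 0.28), Tspan8 (−2.33 ± 0.44) and Serpina3n (−2.29 ± 0.27) fell furthest, all 16 at adjusted p of 0.00011 or less. In all 5082 genes were called (2847 higher, 2235 lower), 2996 without overlap (16.7% of all genes, chance share 0.794%), and 3129 with the series as a block. Cartilage genes rose in 23 of 25 (23 alone, adjusted p = 1.6e-28) and this list held with an estimated correlation (adjusted p = 0.015). Hypertrophic genes rose in 10 of 12 (10 alone, adjusted p = 7e-10, 0.053 estimated) and osteoblast genes in 16 of 19 (17 alone, Smpd3 2.29 ± 0.34, adjusted p = 6.9e-09, 0.29 estimated). Fibrous matrix rose in 17 of 23 (20 alone, Fbn2 2.35 ± 0.25, adjusted p = 7e-10, 0.29 estimated) and osteoclast genes in 11 of 17 (13 alone, adjusted p = 1.8e-06, 0.29 estimated). Morphogen signalling rose in 22 of 39 (25 alone, Frzb 3.07 ± 0.37, adjusted p = 5.3e-11, 0.080 estimated). Endothelial genes rose in 18 of 23 against 1 lower (same alone, adjusted p = 7.1e-09, 0.20 estimated) and proteases in 11 of 19 against 1 lower (12 and 1 alone, adjusted p = 0.0018, 0.29 estimated). Osteocyte genes rose in 8 of 12 against 1 lower (same alone, adjusted p = 0.0038, 0.29 estimated).

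Marrow and immune lists fell in old calluses over these days. Erythroid genes fell in 16 of 20 (17 alone, Car1 −2.61 ± 0.66, adjusted p = 4e-08, 0.29 estimated) and neutrophil genes in 5 of 21 (5 alone, Stfa2 −1.86 ± 0.33, adjusted p = 5.8e-06, 0.29 estimated). B-cell genes fell in 11 of 24 against 1 higher (14 and 1 alone, adjusted p = 3.9e-05, 0.30 estimated) and platelet genes in 6 of 11 (6 alone, Pf4 −1.45 ± 0.29, adjusted p = 2e-04, 0.29 estimated). Macrophage genes fell in 13 of 26 (16 alone, adjusted p = 5.5e-09, 0.10 estimated) and inflammatory genes in 18 of 36 against 1 higher (19 and 1 alone, adjusted p = 3.6e-07, 0.15 estimated). Interferon genes fell in 13 of 29 (15 alone, Oas2 −1.26 ± 0.28, adjusted p = 2.9e-06, 0.29 estimated) and MHC II in 4 of 11 (7 alone, adjusted p = 0.00046, 0.29 estimated). Adipocyte genes fell in 12 of 18 (14 alone, Adipoq −1.58 ± 0.34, adjusted p = 9.6e-06, 0.29 estimated) and muscle regeneration in 6 of 10 (6 alone, adjusted p = 0.0013, 0.29 estimated). Mitosis genes fell in 17 of 39 (33 alone, adjusted p = 8.8e-10, 0.29 estimated), replication genes in 15 of 30 (19 alone, adjusted p = 2.2e-08, 0.29 estimated) and epidermal genes in 3 of 12 (5 alone, adjusted p = 0.038, 0.37 estimated). The epidermal call ended without day 5 replicate 5 or day 10 replicate 1. Mature muscle (1 down) and respiration (0 of 30) did not pass, nor did plasma cells, T and NK cells, mast cells, Schwann cells, hypoxia, secreted factors (6 up, 6 down) and immediate early genes.

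From day 10 to day 20 young calluses lost cartilage. C1qtnf3 (−4.32 ± 0.44, from 10.78 to 6.46), Scrg1 (−3.99 ± 0.45), Matn3 (−3.90 ± 0.41), Cnmd (−3.58 ± 0.36), Hapln1 (−3.51 ± 0.53), Ecrg4 (−3.10 ± 0.33), Ccl8 (−3.03 ± 0.33) and Mfap4 (−2.92 ± 0.28) fell furthest. The ribosomal gene n-R5s136 (2.15 ± 0.46), the osteoblast phosphodiesterase Gdpd2 (2.0 ± 0.31), the sinusoidal scavenger receptor Stab2 (1.91 ± 0.26), Gal (1.70 ± 0.34), the B-cell antigen Ms4a1 (1.65 ± 0.39), Nmb (1.65 ± 0.16), the osteocyte gene Dmp1 (1.60 ± 0.45) and Slit2 (1.57 ± 0.27) rose furthest, all 16 at adjusted p of 0.011 or less. Of the 3298 genes called (1715 higher, 1583 lower), 1992 had no overlap (12.6% of all genes, chance share 0.794%), and 1871 were called with the series as a block, where Dmp1 was not. Cartilage genes fell in 18 of 25 against 1 higher (19 and 1 alone, adjusted p = 1.5e-17, 0.075 estimated) and hypertrophic genes in 4 of 12 (6 alone, Col10a1 −2.71 ± 0.38, adjusted p = 0.0061, 0.46 estimated). Fibrous matrix fell in 10 of 23 against 1 higher (same alone, Col14a1 −2.26 ± 0.27, adjusted p = 7.7e-07, 0.46 estimated). Mature muscle fell in 18 of 29 (23 alone, Myl1 −2.10 ± 0.32, adjusted p = 7.1e-14, 0.34 estimated) and muscle regeneration in 6 of 10 (7 alone, adjusted p = 1.7e-05, 0.26 estimated). Macrophage genes fell in 10 of 26 against 1 higher (10 and 2 alone, C1qb −1.61 ± 0.27, adjusted p = 1.7e-05, 0.34 estimated) and secreted factors in 9 of 16 against 3 higher (12 and 3 alone, adjusted p = 1.7e-05, 0.073 estimated). Erythroid genes rose in 10 of 20 (13 alone, Car1 2.93 ± 0.66, adjusted p = 4.8e-06, 0.46 estimated) and B-cell genes in 8 of 24 against 1 lower (12 and 1 alone, adjusted p = 0.00044, 0.47 estimated). Adipocyte genes rose in 7 of 18 (8 alone, Pparg 1.37 ± 0.18, adjusted p = 0.0014, 0.46 estimated).

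By day 20 other lists moved in young calluses. Osteoclast genes rose in 6 of 17 (9 alone, Dcstamp 1.37 ± 0.23, adjusted p = 0.0027, 0.47 estimated) and osteocyte genes in 7 of 12 against 1 lower (7 and 2 alone, the mineralization gene Mepe 1.40 ± 0.22, adjusted p = 0.017, 0.46 estimated). Both lists lost their call with the series as a block. Endothelial genes rose in 6 of 23 (6 alone, adjusted p = 0.016, 0.54 estimated), a call that ended with the series as a block and without replicate 5. Replication genes rose in 3 of 30 (2 alone, adjusted p = 0.024, 0.77 estimated), a call that ended without any of 4 single arrays. Their median turned from 0.31 to −0.17 with the erythroid covariate, in a fit with a single slope for all days in which many other lists turned too. Hypoxia genes fell in 9 of 23 (10 alone, Adm −1.34 ± 0.19, adjusted p = 0.00028, 0.10 estimated) and proteases in 7 of 19 against 1 higher (7 and 2 alone, adjusted p = 0.0027, 0.46 estimated). Morphogen signalling fell in 11 of 39 against 5 higher (14 and 6 alone, Ptch1 −1.87 ± 0.27, adjusted p = 0.0027, 0.46 estimated) and inflammatory genes in 7 of 36 against 5 higher (8 and 5 alone, Ptgs2 −1.94 ± 0.34, adjusted p = 0.017, 0.47 estimated). Schwann-cell genes fell in 3 of 11 (3 alone, Egfr −1.26 ± 0.17, adjusted p = 0.014, 0.34 estimated). Osteoblasts (3 up, 1 down), mitosis (2 up of 39), interferon (1 up, 3 down), MHC II, neutrophils (0 of 21), plasma cells, T and NK cells (0 of 29), mast cells (3 down, Mcpt4 −1.55 ± 0.22), platelets, epidermis, respiration and immediate early genes did not pass.

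In old calluses the same days brought red-cell transcripts back. Car1 (4.65 ± 0.66, from 5.95 to 10.60), Rhag (4.14 ± 0.67), Ctse (3.99 ± 0.60), Car2 (3.69 ± 0.53), the anion exchanger Slc4a1 (3.60 ± 0.67), Cldn13 (3.47 ± 0.56), Epb42 (3.33 ± 0.54) and Kel (3.19 ± 0.53) rose furthest. Matn3 (−5.01 ± 0.41), Hapln1 (−4.57 ± 0.53), Cnmd (−4.47 ± 0.36), Scrg1 (−4.41 ± 0.45), Clec3a (−4.39 ± 0.52), C1qtnf3 (−4.32 ± 0.44), Ucma (−4.13 ± 0.31) and Acan (−4.03 ± 0.50) fell furthest, all 16 at adjusted p of 0.00017 or less. In all 3481 genes were called (1629 higher, 1852 lower), 1837 without overlap (10.7% of all genes, chance share 0.794%). Cartilage genes fell in 21 of 25 (23 alone, adjusted p = 6.9e-33) and the list held with an estimated correlation (adjusted p = 0.0068). All 20 erythroid genes rose (20 alone, adjusted p = 8.6e-22, 0.096 estimated), as did 11 of 21 neutrophil genes (15 alone, Cxcr2 1.62 ± 0.33, adjusted p = 2.2e-07, 0.24 estimated). T and NK genes rose in 19 of 29 against 1 lower (23 and 1 alone, Nkg7 2.51 ± 0.47, adjusted p = 5e-10, 0.23 estimated), B-cell genes in 11 of 24 against 1 lower (15 and 1 alone, adjusted p = 2.9e-06, 0.24 estimated) and platelet genes in 8 of 11 (10 alone, adjusted p = 1.4e-06, 0.23 estimated). Mast and basophil genes rose in 6 of 12 (6 alone, Mcpt8 2.01 ± 0.37, adjusted p = 0.0027, 0.23 estimated) and adipocyte genes in 11 of 18 (13 alone, Adipoq 2.48 ± 0.34, adjusted p = 1.5e-09, 0.17 estimated).

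Division genes rose in old calluses by day 20: 17 of 39 mitosis genes (26 alone, Mki67 1.44 ± 0.28, Top2a 1.04 ± 0.22, adjusted p = 9.6e-11, 0.25 estimated) and 20 of 30 replication genes (24 alone, adjusted p = 9.6e-11, 0.24 estimated). With the erythroid covariate, which rose over the same days, the medians turned from 0.61 to −0.25 and from 0.72 to −0.26. This fit used a single slope for all days, and many other lists turned in it too. Osteoclast genes rose in 7 of 17 (9 alone, Itgb3 1.21 ± 0.27, adjusted p = 8.8e-05, 0.24 estimated). Interferon genes rose in 6 of 29 (7 alone, Psmb8 0.92 ± 0.17, adjusted p = 0.0026, 0.57 estimated), a call lost without old day 20 replicate 4. Fibrous matrix fell in 15 of 23 (16 alone, adjusted p = 1.2e-12, 0.20 estimated) and hypertrophic genes in 4 of 12 (9 alone, Ihh −1.31 ± 0.19, adjusted p = 3.5e-05, 0.20 estimated). Hypoxia genes fell in 8 of 23 (10 alone, adjusted p = 2.3e-05, 0.066 estimated) and secreted factors in 7 of 16 against 2 higher (9 and 2 alone, adjusted p = 0.00035, 0.096 estimated). Morphogen signalling fell in 14 of 39 against 3 higher (16 and 5 alone, adjusted p = 4e-05, 0.23 estimated) and proteases in 7 of 19 against 1 higher (8 and 1 alone, adjusted p = 0.0027, 0.24 estimated). Immediate early genes fell in 7 of 22 (9 alone, adjusted p = 0.0019, 0.24 estimated), muscle regeneration in 5 of 10 (5 alone, adjusted p = 0.00044, 0.23 estimated) and mature muscle in 2 of 29 (2 alone, adjusted p = 0.0022, 0.60 estimated, lost without replicate 2). Schwann-cell genes passed as lower (4 of 11, 5 alone, adjusted p = 0.027, 0.24 estimated) although their median was 0.03, the mean being −0.30. Among lists that passed in any contrast this was the only difference in sign between median, mean and test. Among those that did not pass, such lists had medians between −0.17 and 0.17. Osteoblasts (1 up, 1 down), osteocytes (2 and 2), inflammatory genes (2 and 7), MHC II, macrophages (2 and 2), plasma cells, endothelium, epidermis and respiration did not pass.

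**Figure D2:**
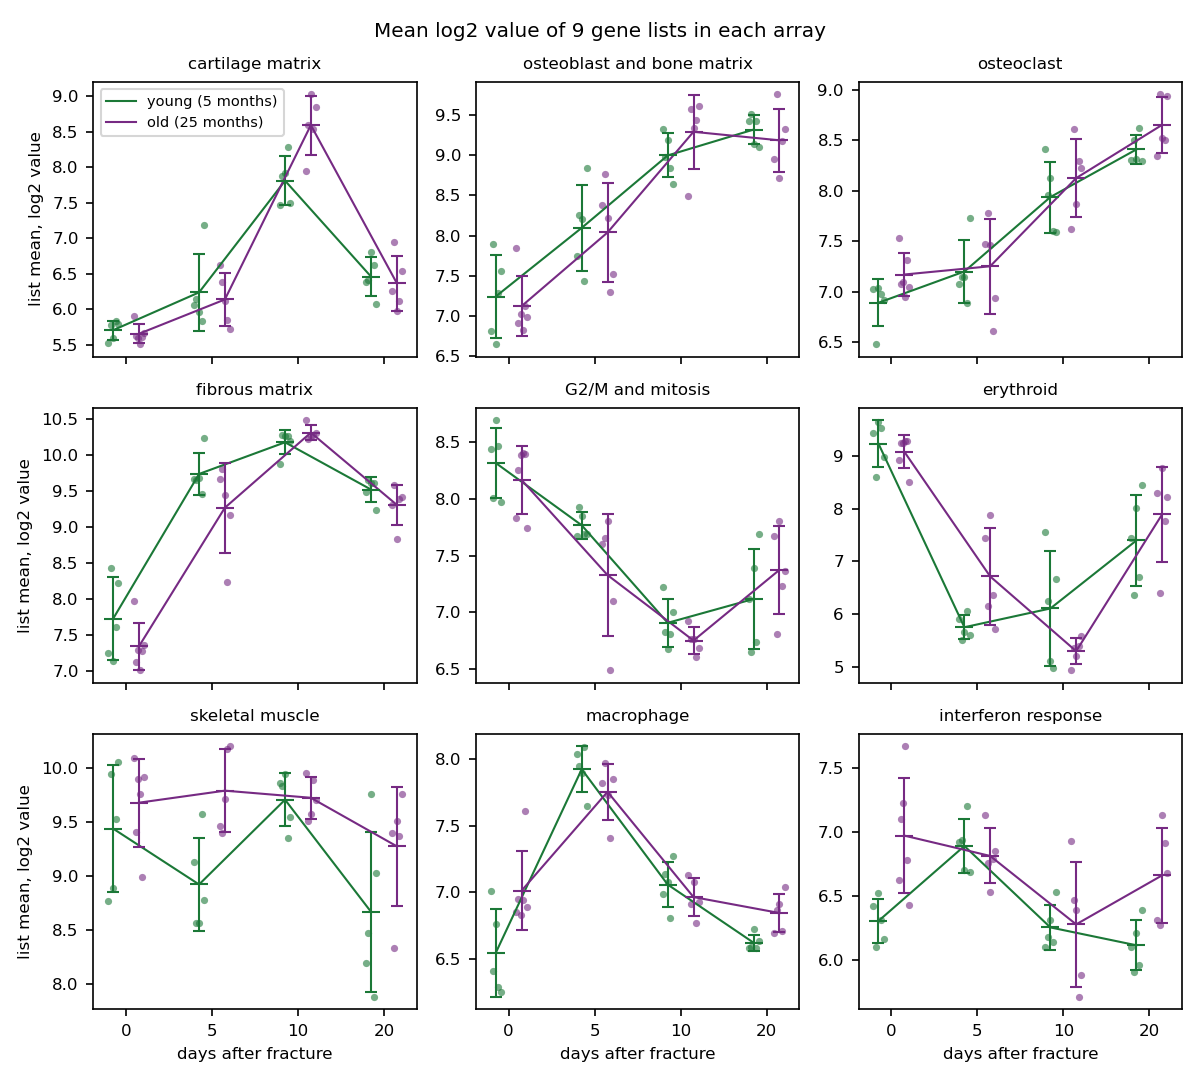
Means of 9 gene lists per array by age and day. Points, arrays; bars, group mean ± SD; lines join the means of an age.

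Changes in young and old mice were correlated. Across genes, which are not independent replicates, the Pearson correlation of the young and the old change was 0.913 (jackknife SE over arrays 0.048) from day 0 to 5, 0.735 (0.093) from day 5 to 10 and 0.749 (0.114) from day 10 to 20. Genes that rose at both ages numbered 2936, 1401 and 586 in the 3 steps, against 729, 307 and 140 if the ages were independent. Those that fell at both numbered 2120, 1067 and 952 (511, 215 and 147 if independent), and 1, 8 and 1 were called in opposite directions.

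Before fracture, old bones carried more interferon, antigen presentation and macrophage transcripts. Ccl8 was higher by 1.93 ± 0.32 (6.32 ± 0.75 SD in 6 old arrays, 4.39 ± 0.65 in 5 young, adjusted p = 0.0051), the interferon-induced Rtp4 by 1.35 ± 0.28, Oasl2 by 1.34 ± 0.28 and the nucleic acid sensor Zbp1 by 1.14 ± 0.24 (each adjusted p = 0.045). The cytotoxic T-cell granzyme Gzmk (0.87 ± 0.13, adjusted p = 0.002), the macrophage gene Aif1 (0.87 ± 0.18, 0.045), the MHC class I gene H2-Q4 (0.85 ± 0.16, 0.019), the MHC class II gene H2-Ab1 (0.88 ± 0.18, 0.044) and Fgfbp3 (0.57 ± 0.12, 0.045) were higher too. The other 3 genes called, Ubd (1.82), the complement gene C4b (0.97) and Calml3 (0.76), lie outside the naming rule and were chosen after the values were seen. All 12 genes called were higher in old mice. Of these 8 had no overlap. Over all genes 102 had none (0.512%), near the chance share of 0.433%, and 1306 genes had an unadjusted p under 0.05. Gzmk kept its call without any single array. Ccl8 lost it only without young replicate 4, H2-Q4 in 4 of 11 such fits and the others in 6 or 7. A limma fit on the day 0 groups alone called 0 genes, and leaving out single arrays gave 1 (without young replicate 4) to 31 (without young replicate 1). Within the numbering series 0 genes (high numbers, 2 old against 3 young arrays, 747 with unadjusted p under 0.05) and 21 (lettered, 3 against 2) were called, with Ccl8 at 1.22 and 2.80. The lettered names of day 0 began with H in young and with NO or NON in old mice. That comparison therefore does not hold the lettering constant.

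The lists at day 0 were broader than the single genes. All 29 interferon genes had positive values and 3 rose (23 alone, median 0.62, within-series 0.74 and 0.74, adjusted p = 1.4e-27, 0.039 estimated). MHC II genes had a median of 0.55 (1 of 11 rose, 9 alone, within-series 0.45 and 0.90, adjusted p = 2.7e-14, 0.027 estimated). Macrophage genes had a median of 0.51 (0 of 26 rose by limma, 11 alone, within-series 0.21 and 0.80, adjusted p = 2.7e-14, 0.027 estimated), with C1qa at 1.21 ± 0.27 and Adgre1 at 0.78 ± 0.20, neither passing. These 3 held with an estimated correlation. The second within-series value of each comes from the lettered arrays, whose lettering differed between the ages. T and NK genes (1 of 29, 6 alone, median 0.35, adjusted p = 2.7e-14, 0.19 estimated), platelet genes (0 of 11, 1 alone, 0.58, Vwf 0.58 ± 0.19, adjusted p = 4.3e-07, 0.37 estimated) passed as higher. So did inflammatory genes (1 of 36, 1 alone, 0.14, adjusted p = 0.00033, 0.40 estimated) and osteoclast genes (0 of 17, 0 alone, 0.30, Acp5 0.76 ± 0.32, adjusted p = 0.00033, 0.49 estimated). Fibrous matrix passed as lower (0 of 23, 3 alone, −0.32, Lum −0.92 ± 0.29, adjusted p = 8.4e-08, 0.47 estimated). The calls of mitosis (−0.16, adjusted p = 0.0013, 0.83 estimated), mature muscle (0.22, 0.0038, 0.83), adipocytes (0.21, 0.0073, 0.67), plasma cells (0.20, 0.0029, 0.37) and osteocytes (−0.18, 0.025, 0.60) each ended without a single array. Among these were young replicate 3 for the first 3, old replicate 5 for plasma cells and young replicate 2 for osteocytes. The remaining 18 lists, among them cartilage, erythroid, neutrophil and replication genes, did not pass.

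At day 5, old calluses differed from young ones in 91 genes, 72 higher and 19 lower. The salivary-type amylase Amy1 (1.82 ± 0.34, 7.55 ± 0.78 SD in old, 5.72 ± 0.40 in young, 5 arrays each, adjusted p = 0.014), the kinase Camk2b (1.40 ± 0.25, 0.014), Gca (1.27 ± 0.28, 0.038), the muscle heat shock gene Hspb7 (1.26 ± 0.30, 0.045), and Ppp1r1a (1.25 ± 0.28, 0.038) were highest. The chromatin organizer Satb1 (1.18 ± 0.19, 0.0044), Inmt (1.16 ± 0.27, 0.038), the muscle apoptosis repressor Nol3 (1.14 ± 0.19, 0.0053), the acute-phase gene Orm1 (1.07 ± 0.24, 0.038) and Hipk2 (0.97 ± 0.20, 0.032) followed. The small nucleolar RNAs Snora73a (−1.62 ± 0.36, 0.038) and Snora73b (−1.60 ± 0.37, 0.038), the retinoic acid binder Crabp1 (−1.43 ± 0.27, 0.014), and Fcrls (−1.03 ± 0.20, 0.017) were lowest. Tubb2b (−0.99 ± 0.22, 0.038), Car13 (−0.76 ± 0.18, 0.038), Nnmt (−0.75 ± 0.16, 0.033), Elovl6 (−0.69 ± 0.17, 0.046), Ptgr1 (−0.68 ± 0.15, 0.038) and Ccn5 (−0.59 ± 0.14, 0.038) were lower as well. Of the 91 genes 45 had no overlap, and of all genes 439 (2.2%, chance share 0.794%). Satb1 lost its call only without old replicate 4, and Nol3 without old replicate 4 or 5. Every other gene named lost it in 4 to 7 of 10 left-out fits, and all but Satb1 lost it with the muscle list mean as a covariate. The count ran from 1 (without old replicate 4) to 490 (without old replicate 2), and a limma fit on the day 5 groups alone called 0 genes, where 2988 had an unadjusted p under 0.05 in the full fit. Within the lettered series (4 old against 5 young arrays) 209 genes were called.

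Muscle genes were higher and division genes lower in old calluses at day 5. Mature muscle had a median of 0.94 (0 of 29 rose by limma, 26 alone, within-series 1.15, adjusted p = 9.7e-19, 0.67 estimated), with Mybpc2 at 1.58 ± 0.42 and Ryr1 at 1.37 ± 0.37, neither passing. Respiration genes had 0.28 (0 of 30, 4 alone, adjusted p = 4.3e-11, 0.67 estimated), and their call ended with muscle as a covariate. Mitosis genes had −0.46 (1 of 39 fell, Melk −0.56 ± 0.13, 3 alone, within-series −0.54, adjusted p = 8.5e-12, 0.67 estimated), a value of −0.24 without old replicate 4. Replication genes had −0.27 (0 of 30, adjusted p = 0.00015, 0.67 estimated), a call lost without old replicate 4. Erythroid genes had 1.07 (0 of 20, 4 alone, Sptb 1.33, not passing, adjusted p = 1.9e-09, 0.67 estimated) and neutrophil genes 0.62 (0 of 21, adjusted p = 5.7e-06, 0.67 estimated), the latter ending with erythroid genes as a covariate. Platelet genes had 0.55 (adjusted p = 0.0013, 0.67 estimated, lost without old replicate 3, −0.05 with the erythroid covariate), endothelial genes 0.11 (adjusted p = 0.0038, 0.67 estimated) and adipocyte genes 0.17 (adjusted p = 0.0099, 0.67 estimated, lost without young or old replicate 4). Fibrous matrix had −0.43 (0 of 23, 1 alone, adjusted p = 1.5e-06, 0.67 estimated). Among hypertrophic genes, which did not pass as a list (median 0.06), the transcription factor Mef2c was higher by 0.91 ± 0.17 (adjusted p = 0.014), a call lost in 4 of 10 left-out fits. Whether its transcripts came from cartilage, muscle or other tissue was not tested. No list held with an estimated correlation. The other 21 lists, among them the inflammatory, interferon and macrophage genes, did not pass.

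At day 10 old calluses held more cartilage and fewer mast-cell transcripts. The cartilage genes Ucma (1.68 ± 0.31, adjusted p = 0.027), Mia (1.47 ± 0.30, 0.037) and Matn1 (0.97 ± 0.18, 0.027), the magnesium transporter Cnnm4 (0.66 ± 0.14, 0.041) and Tmco3 (0.42 ± 0.08, 0.031) were higher. The mast-cell protease Mcpt4 (−1.26 ± 0.22, 6.08 ± 0.33 SD in old, 7.34 ± 0.50 in young, 5 arrays each, adjusted p = 0.022), the fibroblast gene Pi16 (−1.0 ± 0.19, 0.027) and the glutathione transferase Mgst1 (−0.92 ± 0.17, 0.027) were lower. Scube1 (1.10, higher) and Tmeff2 (−0.95, lower) complete the 10 genes called (6 higher, 4 lower) and were chosen after the values were seen. Of the 10, 5 had no overlap, and of all genes 381 (1.91%, chance share 0.794%). In all, 1543 genes had an unadjusted p under 0.05. Without young or old replicate 5 limma called 0 genes, and without old replicate 1 it called 49. Mcpt4 lost its call in 3 of 10 such fits (young replicates 2 and 5, old replicate 5), Ucma, Matn1, Mgst1 and Tmco3 in 6, Pi16 in 7, Mia in 8 and Cnnm4 in 9. An ANOVA test and a fit on the day 10 groups alone each called 0. Ucma stood at 1.03 in the high series (3 against 3 arrays) and 2.67 in the low series (2 against 2), Mia at 0.80 and 2.49, Matn1 at 0.45 and 1.75, with 3 genes called in each series.

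As a list, cartilage matrix was higher at day 10 (3 of 25 rose, 18 alone, 24 positive, median 0.84, adjusted p = 5.8e-23, 0.046 estimated), at 0.50 in the high and 1.03 in the low series. Mast and basophil genes were lower (1 of 12 fell, 4 alone, −0.43, within-series −0.29 and −0.34, adjusted p = 3.2e-07, 0.046 estimated). Both held with an estimated correlation. Hypertrophic genes had 0.44 (0 of 12, 2 alone, Ihh 0.65 and Scin 0.73, neither passing, adjusted p = 6.3e-06, 0.18 estimated) and hypoxia genes 0.13 (0 of 23, 3 alone, Slc2a1 0.70, not passing, adjusted p = 0.00075, 0.14 estimated). Erythroid genes had −0.87 (0 of 20, Alas2 −1.0, not passing, within-series −0.26 in the high and −1.69 in the low series, adjusted p = 1.8e-09, 0.48 estimated) and adipocyte genes −0.25 (0 of 18, 3 alone, Adipoq −1.32 ± 0.34, not passing, adjusted p = 6.2e-06, 0.48 estimated). Osteoblast (0.26, adjusted p = 0.0047), endothelial (0.21, 0.014), neutrophil (−0.28, 0.00095), B-cell (−0.18, 0.0045), mitosis (−0.19, 0.0024), replication (−0.12, 0.0069) and epidermal genes (−0.14, 0.032) passed with adjusted p = 0.81 each with an estimated correlation. Mitosis, replication and neutrophil values turned positive with erythroid genes as a covariate. Osteoblast and endothelial calls ended without young or old replicate 5, those of neutrophil, B-cell and replication genes without young replicate 1. The remaining 18 lists, among them interferon, MHC II and macrophage genes, did not pass.

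At day 20 a single gene was called: Ccl8 was higher in old calluses by 1.9 ± 0.33 (7.71 ± 0.34 SD in old, 5.81 ± 0.34 in young, 5 arrays each, adjusted p = 0.032), without overlap between the ages. Of all genes 297 had none (1.49%, chance share 0.794%). Ccl8 lost its call without any of 5 single arrays (young replicates 1, 2 and 4, old replicates 3 and 5), and the count ran from 0 to 82 (without old replicate 1). The call also ended with the ANOVA test and in the fit without 2 arrays. Unadjusted p under 0.05 was reached by 2920 genes. Several immune lists were higher, but not B-cell (0.01, adjusted p = 0.58) or plasma-cell genes (0.08, 0.38). Interferon genes had a median of 0.53 (0 of 29 by limma, 9 alone, Zbp1 1.20 ± 0.25 and Cxcl9 1.87 ± 0.48, neither passing, adjusted p = 4.5e-13, 0.32 estimated). T and NK cells had 0.59 (0 of 29, 16 higher and 1 lower alone, Ccl5 1.82 ± 0.42, not passing, adjusted p = 4.5e-13, 0.32 estimated) and neutrophils 0.71 (0 of 21, 7 alone, Lcn2 1.66, not passing, adjusted p = 4.3e-12, 0.32 estimated). Without old replicate 3 the T and NK value was 0.20. Platelet genes had 1.04 (0 of 11, 11 alone, Pf4 1.38 ± 0.29, not passing, adjusted p = 4.3e-12, 0.32 estimated) and mature muscle 0.65 (5 of 29 alone, adjusted p = 1.9e-11, 0.46 estimated). Macrophages had 0.22 (C1qb 0.81, not passing, adjusted p = 0.00033, 0.46 estimated), MHC II 0.27 (3 of 11 alone, adjusted p = 0.0069, 0.60 estimated) and inflammatory genes 0.08 (1 of 36, adjusted p = 0.0069, 0.60 estimated). Mitosis (0.23, adjusted p = 8.9e-07), replication (0.25, 3.2e-05), erythroid (0.48, 0.00017) and osteoclast genes (0.30, 0.0032) passed as higher with adjusted p = 0.62 each with an estimated correlation, and the replication call ended with erythroid genes as a covariate. Hypoxia (0.11, adjusted p = 0.037, 0.46 estimated), respiration (0.09, 0.015, 0.71), mast-cell (0.07, 0.013, 0.46) and, as lower, endothelial genes (−0.23, 0.012, 0.66) passed. They lost their call without a single array, among them young replicate 2 for the first pair, young replicate 4 for mast cells and old replicate 1 for endothelium. With the muscle list mean as a covariate the respiration median turned to −0.12. No list held with an estimated correlation, and the other 15 lists did not pass.

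**Figure D3:**
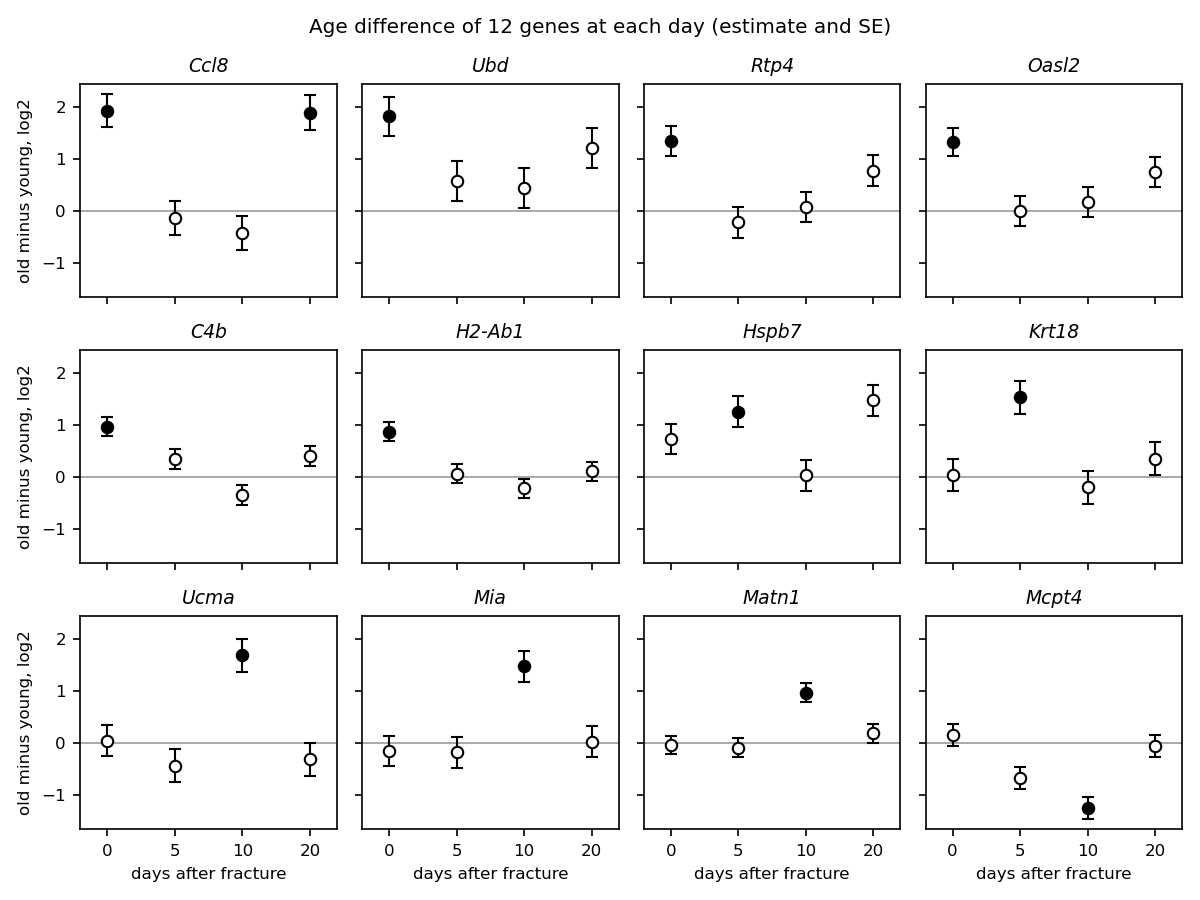
Old minus young log2 difference ± SE of 12 genes at each day. Filled points, adjusted p under 0.05; open points did not pass.

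Whether a step differed between ages was tested directly. From day 5 to day 10, Bcat1, which starts the breakdown of branched-chain amino acids, rose more in old than in young calluses by 1.34 ± 0.25 and Fam207a by 0.80 ± 0.15 (each adjusted p = 0.045). Both calls ended with the numbering series as a block (1.35 ± 0.26 and 0.78 ± 0.15, adjusted p = 0.0698), and no series occurred in both young groups of this step. Each lost its call in 14 of 20 left-out fits, and the count ran from 0 to 47 (without old day 5 replicate 2). Limma called 0 genes in the steps from day 0 to 5 (1562 with unadjusted p under 0.05) and day 10 to 20 (1895), against 2 of 2203 from day 5 to 10. The smallest p values belonged to Camk1 (−0.73 ± 0.15), Satb1 (1.23 ± 0.27), Aif1 (−1.19 ± 0.26), Ccl8 (−2.06 ± 0.46) and Adcy2 (0.98 ± 0.22) in the first step. In the last they belonged to Mgst1 (1.21 ± 0.24), Ccl8 (2.32 ± 0.47), Pi16 (1.29), Tnfrsf10b (−0.79) and Txnrd1 (−0.56), and none of the 10 passed.

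Among lists, only mast and basophil genes from day 10 to 20 held with an estimated correlation. Over the list alone 8 of 12 gained more in old mice (0 over all genes), with a median of 0.65 (adjusted p = 3.1e-09, 0.034 estimated). The median old minus young difference of this list was −0.43 at day 10 and 0.07 at day 20. In the first step macrophage genes rose less in old mice (−0.68, 11 of 26 alone, adjusted p = 5.7e-12, 0.12 estimated). List means of interferon (−0.60, 11 of 29 alone, adjusted p = 5.9e-15, 0.35 estimated) and MHC II genes (−0.54, 4 of 11 alone, adjusted p = 8.9e-06, 0.35 estimated) went up in young mice (6.30 to 6.89, 7.36 to 7.51) and down in old mice (6.97 to 6.81, 7.96 to 7.59). Erythroid genes fell less in old mice (1.33, adjusted p = 5.6e-10, 0.55 estimated). Mature muscle (0.68, adjusted p = 4.7e-09, 0.57 estimated) went from 9.44 to 8.92 in young and from 9.68 to 9.79 in old mice. In the second step cartilage genes gained more (0.89, 11 of 25 alone, adjusted p = 1.6e-12, 0.35 estimated), with fibrous matrix (0.67, 5 of 23 alone, adjusted p = 3.9e-07, 0.55 estimated). Mitosis genes fell less in old mice (0.31, adjusted p = 0.0011, 0.88 estimated), opposite in sign to the first step. B-cell, platelet, mast-cell and epidermal lists passed as lower with the preset correlation only. Erythroid (−1.94, 16 of 20 alone, adjusted p = 1.3e-17, 0.35 estimated), neutrophil (−1.0, adjusted p = 4.2e-09, 0.40 estimated) and adipocyte genes (−0.39, 3 of 18 alone, adjusted p = 1.5e-07, 0.39 estimated) fell in old mice, while the young list means went from 5.75 to 6.10, 7.94 to 7.97 and 5.99 to 5.96. Mature muscle (−0.94, adjusted p = 9.8e-13, 0.40 estimated) went from 8.92 to 9.70 in young and from 9.79 to 9.73 in old mice. Respiration (−0.29, adjusted p = 4.2e-09, 0.42 estimated) went from 9.20 to 9.56 and from 9.50 to 9.52. From day 10 to 20 cartilage lost more (−0.91, 10 of 25 alone, adjusted p = 9.1e-12, 0.18 estimated). Neutrophil genes rose in old mice (1.29, 8 of 21 alone, adjusted p = 3.5e-15, 0.18 estimated), where young list means went from 7.97 to 7.85. Platelets (1.20, 4 of 11 alone, adjusted p = 1.4e-10, 0.18 estimated), T and NK cells (0.54, adjusted p = 2.8e-10, 0.26 estimated) and mitosis genes (0.44, adjusted p = 3.3e-10, 0.43 estimated) gained more, as did erythroid genes (1.27, adjusted p = 4.2e-13, 0.26 estimated). Mature muscle fell less (0.60, adjusted p = 1.7e-08, 0.43 estimated). Further lists passed with the preset correlation only. From day 0 to 5 these were neutrophil (0.59), respiration (0.26), T and NK (−0.32), inflammatory (−0.24), secreted-factor (−0.22) and replication genes (−0.22). From day 10 to 20 interferon (0.48), replication (0.39), macrophage (0.36), MHC II (0.33), adipocyte (0.28) and respiration genes (0.10) passed as higher. Osteoblast (−0.45), endothelial (−0.34) and fibrous matrix genes (−0.33) passed as lower. The mitosis difference of the first step (−0.30, adjusted p = 0.00016, 0.88 estimated) ended without old day 5 replicate 4. List means per array were also permuted between ages within each of the 4 days. The smallest exact p possible was 0.0043 at day 0 and 0.0079 at the other days, so a single list could not pass when adjusted over all lists and days (smallest adjusted p 0.232). Those limits were reached, without overlap of the ages, by secreted factors at day 0 (old minus young 0.18) and adipocyte genes at day 10 (−0.33). The secreted-factor list did not pass by camera at day 0 (median 0.05, 10 of 16 members positive, adjusted p = 0.07). Its only member called was Ccl8 (1.93), which weighs heavily in that mean. Changes of list means by step were permuted too. Adjusted over all lists and steps, mast and basophil genes from day 10 to 20 did not pass (permutation p = 0.0058, adjusted p = 0.181). Nor did macrophage genes from day 0 to 5 (0.01, 0.212) or cartilage genes from day 5 to 10 (0.043, 0.252).

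The authors' deposited table, which tests probe sets, had 25, 20, 1 and 0 of them at adjusted p under 0.05 between ages at days 0, 5, 10 and 20. For its factors it had 168 for age, 20235 for day and 1 for their interaction.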

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

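The tests of explanations and the splits in this part were chosen after the result was seen, except the macrophage and T-cell covariates of the day 0 interferon difference over all arrays, which were set before those fits. The age-by-step contrasts with their list tests, the series block and the fits that leave out an array were fixed beforehand.

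Arrays far from the rest of their group were sought by a Dixon test on list means and named genes, which gives about 1 in 20 groups by chance. Among list means 16 of 248 groups had such an array against about 12 by chance, and 21 of 332 groups in all. Old day 0 replicate 1 stood apart in hypertrophic cartilage (7.10), osteoblast (7.85) and fibrous matrix (7.97), old day 10 replicate 1 stood apart in hypertrophic cartilage (8.16) and osteoblast genes (8.49), and young day 5 replicate 5 in cartilage (7.18), hypertrophic cartilage (7.76) and fibrous matrix (10.23). Young day 10 replicate 1 stood apart in fibrous matrix (9.88), young day 0 replicate 2 in osteoclast genes (6.48), and old day 0 replicate 5 in macrophage (7.61) and plasma-cell genes (6.96). Old day 20 replicate 2 stood apart in neutrophil (8.04) and muscle genes (8.33), old day 5 replicate 5 in epidermal genes (6.11) and young day 10 replicate 2 in immediate early genes (7.52). Single genes were Oasl2 in young day 0 replicate 2 (5.67), Camk2b (6.53) and Hipk2 (8.08) in young day 5 replicate 4, Crabp1 in young day 5 replicate 3 (9.0) and Elovl6 in young day 5 replicate 5 (7.39). The skeletal lists moved together in 3 of these arrays, so they are not independent findings.

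Steps in time were flagged where a gene was called, or where a list passed fry or camera with an estimated correlation. More lists passed camera with the preset correlation, as given above. Flagged lists were macrophage from day 0 to 5 (−0.68, fry adjusted p = 0.033, camera adjusted p = 0.12 estimated) and mast and basophil from day 10 to 20 (0.65). With list means permuted between ages, neither passed over all lists and steps (permutation p = 0.01 and 0.0058, adjusted p = 0.212 and 0.181). Bcat1 (1.34) and Fam207a (0.80) were flagged from day 5 to 10. Their calls ended with the numbering series as a block (each adjusted p = 0.0698).

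The higher interferon list of old bones before fracture could come from a single array, but without old day 0 replicate 4 its median was 0.44 against 0.62 (exact permutation p = 0.016 for list means). A larger number of macrophages might raise it. With the macrophage list mean as a covariate the age difference of list means was 0.48 ± 0.22 SE, from 0.67 ± 0.19, which speaks against that as the whole cause. With the T and NK list mean as a covariate it was 0.46 ± 0.19, with the same reading. Slopes fitted on the 11 arrays of day 0 alone gave 0.64 ± 0.29 and 0.41 ± 0.29, the latter too imprecise to tell.

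The higher cartilage list of old calluses at day 10 could rest on an array or on the numbering series, whose meaning the labels do not give. Without young day 10 replicate 1 its median was 0.66 against 0.84 (exact permutation p = 0.04), and the smaller value within a numbering series was 0.50 (exact p = 0.033 with age permuted within series). A lower share of other cells would raise osteoblast and fibrous genes alike, yet cartilage exceeded their mean by 0.57 more in old mice (exact p = 0.032). A single array thus did not account for the difference. The series test rested on 3 against 3 and 2 against 2 arrays, with medians of 0.50 and 1.03. The series could therefore still contribute to its size. The last test compared cartilage with osteoblast and fibrous genes only, so other differences in the tissue sampled stay open.

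By camera with the preset correlation, old calluses at day 5 had a higher muscle and a lower mitosis list. With all arrays the exact permutation p of list means was 0.024 for muscle and 0.087 for mitosis. The mitosis difference thus did not pass by permutation before any array was left out. The muscle median without old day 5 replicate 5 was 0.81 against 0.94 (exact permutation p = 0.04), so a single array does not account for it. The mitosis median without old day 5 replicate 4 was −0.24 against −0.46 (exact p = 0.13), and whether that array makes the difference cannot be told. More muscle in the sample might dilute dividing cells. Across the 10 arrays of day 5 the mitosis and muscle list means had a Pearson correlation of −0.76 (permutation p adjusted over 16 tests 0.0068), and −0.65 within ages. The Spearman value of −0.68 did not pass (adjusted p = 0.068). With the muscle list mean as a covariate on these arrays the difference of mitosis means was 0.10 ± 0.31 SE, from −0.44 ± 0.25, so dilution could account for it. A slope over all days was −0.03, and that fit moved little (−0.41 ± 0.24). Correlations on the other days were −0.74 (day 0), 0.03 (day 10) and 0.75 (day 20). An effect of age on division stays open, since muscle itself differed between ages.

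Splits of the same arrays asked how often a grouping calls as many genes, counting the real grouping among 100. Between ages as many were called by 2 splits at day 5 (91 genes, highest other 601) and 4 at day 10 (10 genes, 24). At day 0 as many were called by 10 splits (12 genes, 1550) and at day 20 by 17 (1 gene, 339). These shares are not adjusted over the 4 age contrasts, so they do not exclude chance at any day. For every step in time only the real grouping reached its count. In young mice 7229 stood against a highest other of 3673, 4072 against 1660 and 3298 against 1001. In old mice 6790 stood against 5128, 5082 against 1503 and 3481 against 2553. For age by step from day 5 to 10, 6 splits called at least the 2 genes of the real grouping (highest other 12), so chance is not excluded. In the first and last step 0 genes were called. Every split calls at least as many, so those counts could not be tested (highest other 81 and 8). At day 0 and day 20 the split with most genes mixed the ages (2 young and 3 old arrays against 3 and 3, 3 and 2 against 2 and 3). These splits called 1550 genes against 12 and 339 against 1. Whether the samples hold a structure other than age was not tested. At days 5 and 10 the split with most genes was the age grouping with young replicate 4 and old replicate 1 exchanged. That split largely followed age, and why it called more genes is open.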

How the results depend on the processing

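Alternatives added after results were seen were the fit without 2 arrays, all probe sets, and the covariate fits; the others were fixed beforehand. The cause was not tested for any value that changed. The planned exchange of one deposited value table for the other changed nothing, because both are identical.

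Counts of genes differing between ages, day 0 (12 genes): median centring 6, ANOVA test 4, fit on the groups compared 0, replicate block 3, numbering series as a block 7, at least 2-fold 5, muscle covariate 19, all probe sets 33. Leaving out an array gave 1 to 31. Day 5 (91): genes above the lower quartile of means 154, above the median 202, ANOVA test 14, fit on the groups compared 0, array quality weights 457, at least 2-fold 28, without 2 arrays 3, muscle covariate 2, erythroid covariate 261. Leaving out an array gave 1 to 490.

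Day 10 (10): ANOVA test 0, fit on the groups compared 0, array quality weights 788, at least 2-fold 5, erythroid covariate 2. Leaving out an array gave 0 to 49. Day 20 (1): quantile normalization 3, genes above the lower quartile 2, above the median 6, ANOVA test 0, trend and robust 2, array quality weights 5, replicate block 2, without 2 arrays 0, muscle covariate 6, all probe sets 0. Leaving out an array gave 0 to 82.

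Counts changed with time moved beyond 1.5 times only with a minimum of 2-fold and with the series block. At least 2-fold left 1699 (young, day 0 to 5), 524 (day 5 to 10), 455 (day 10 to 20), and 1341, 829 and 617 in old mice. The series block gave 1852 and 1871 in young mice (day 5 to 10, day 10 to 20) and 3129 in old mice (day 5 to 10). Leaving out an array kept each within 1.5 times.

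For age by step, day 0 to 5 (0): array quality weights 2, leaving out an array 0 to 1. Day 5 to 10 (2): quantile normalization 5, median centring 5, genes above the lower quartile 4, above the median 8, ANOVA test 0, trend and robust 0, fit on the groups compared 0, array quality weights 158, replicate block 7, series block 0, at least 2-fold 1, without 2 arrays 1, all probe sets 0, leaving out an array 0 to 47. Day 10 to 20 (0): array quality weights 3, leaving out an array 0 to 5. The mean of a gene's probe sets moved no count, and no alternative moved a correlation of young and old steps.

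List tests that turned direction are given where the main fit or the alternative passed. With array quality weights the test of osteoblast genes at day 5 turned to higher, its median going from 0.01 to 0.23. With the erythroid covariate the platelet median at day 5 turned to −0.05. At day 10 replication turned to 0.15, mitosis to 0.09, neutrophil to 0.06 and platelet genes to 0.30. With the muscle covariate, respiration at day 20 turned to −0.12. Fibrous matrix, age by step from day 0 to 5, turned to 0.16 without the 2 arrays and without old day 5 replicate 4 alone.

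Among 403 list tests an estimated correlation weakened 200, fry 92 (6 stronger), array quality weights 14 (25 stronger), the genes above the median 22 (7 stronger), those above the lower quartile 10 (5 stronger), the series block 8 (13 stronger), quantile normalization 5 (10 stronger), the fit on the groups compared 5 (20 stronger), the replicate block 4 (1 stronger) and lists without shared members 2 (4 stronger). The covariates weakened 6 (erythroid, 6 stronger) and 3 (muscle, 6 stronger), the fit without 2 arrays 7 (9 stronger), and leaving out an array 88 of its tests (159 stronger, 4805 same). Among 1150 gene values the series block weakened 110, the fit on the groups compared 90, the ANOVA test 49, the fit without 2 arrays 40, the muscle covariate 21, the replicate block 19, quantile normalization 17, median centring 11, the erythroid covariate 10, array quality weights 9 (56 stronger), trend and robust 5 and the mean of probe sets 2. Leaving out an array weakened 629 of its gene tests and strengthened 82, with 12970 the same.

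The covariate fits were first run on all contrasts. After many lists of time contrasts were seen to turn with the erythroid covariate, covariates were kept for age contrasts only, because erythroid means differ by day. The mitosis values seen were 0.70 and −0.01 from day 0 to 5 in young and old mice (−0.55 and −0.86 without it) and −0.28 and −0.25 from day 10 to 20 (0.21 and 0.61). Replication values were 0.71 and 0.11 (−0.62 and −0.80) and −0.17 and −0.26 (0.31 and 0.72).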

Other observations

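The age difference averaged over the 4 days, and the relation of mitosis to erythroid genes, were chosen after the results by day had been seen.

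Averaged over days 0, 5, 10 and 20, limma called 131 genes higher and 64 lower in old mice, and 171 of these had the same sign at all 4 days. Choosing genes on their average favours a shared sign, and its share over all genes was not counted. The muscle heat shock gene Hspb7 (0.87 ± 0.15 SE, adjusted p = 0.0093), the glucose transporter Slc2a1 (0.43 ± 0.07, 0.0093), the peptide transporter Tap1 (0.56 ± 0.10, 0.016), the ubiquitin-like Ubd (1.02 ± 0.19, 0.016), the T-cell chemokine Ccl5 (1.05 ± 0.21, 0.02), Gzmk (0.34 ± 0.07, 0.02), the angiogenic glycoprotein Lrg1 (0.88 ± 0.18, 0.02) and Cxcl9 (1.11 ± 0.24, 0.022) were higher. Tmeff2 (−0.52 ± 0.09, 0.0093), Il1rl2 (−0.42 ± 0.08, 0.011), Crabp1 (−0.70 ± 0.13, 0.017) and the mast-cell proteases Cpa3 (−0.46 ± 0.10, 0.027) and Mcpt4 (−0.46 ± 0.11, 0.029) were lower. The mast and basophil list as a whole did not pass (3 of 12 fell, median 0.04, camera adjusted p = 0.78), and Mcpt4 stood at 0.15 at day 0.

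Ccl5 stood at 1.58, 0.71, 0.11 and 1.82 on the 4 days and Cxcl9 at 1.97, 0.53, 0.06 and 1.87, so the average came chiefly from day 0 and day 20. The invariant chain gene Cd74 (0.63 ± 0.16, adjusted p = 0.04) and Cd3g (0.75 ± 0.17, 0.028) had the same course. Across genes, which are not independent replicates, the age differences of day 0 and day 20 had a Pearson correlation of 0.403, the highest of the 6 pairs of days. The list medians were 0.25 for interferon (3 members rose) and 0.26 for T and NK genes (3 rose), each with an adjusted p of 0.29 with an estimated correlation. Larger medians were those of platelet (0.56, 1 rose) and mature muscle genes (0.43, 2 rose), with the same estimated value, and no list passed with an estimated correlation. Without old day 5 replicate 4 and old day 20 replicate 3, 101 genes were called. Among 100 splits only the real grouping reached the total of both counts (highest other 29).

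Division genes may follow marrow content rather than callus growth at some days. Across arrays the mitosis list mean had a Pearson correlation with the erythroid list mean of 0.92 at day 0 (n = 11, permutation p = 1e-04, adjusted over 16 tests 8e-04) and 0.97 at day 20 (n = 10, permutation p = 1e-05, the smallest possible with the resamples drawn, adjusted 0.00016). At day 5 it was −0.01 (n = 10, permutation p = 0.97), 0.49 within ages, −0.63 without the 2 farthest arrays and −0.43 by Spearman rank, which leaves it open. At day 10 it was 0.77 (n = 10, permutation p = 0.013), 0.71 within ages, 0.35 by Spearman rank and −0.09 without the 2 farthest arrays, which is open too. At day 20 the mitosis list mean also correlated with the neutrophil (Pearson 0.85, permutation p adjusted over 16 tests 0.0046) and mature muscle list means (0.75, 0.036). The relation was therefore not particular to erythroid genes. A candidate explanation for the rise of mitosis genes in old calluses from day 10 to 20 is returning marrow, which was not tested here. Counting dividing cells by type in sections would test it.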
